A study of Bos taurus with 14 samples.

How the data were processed

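Mammary tissue was taken by biopsy from Holstein cows in the dry period, the weeks without milking before calving. Per the labels, milking ended about 60 d before the predicted calving date, and cows were assigned at random to a long day photoperiod (LD, 16 h of light and 8 h of dark) or a short day photoperiod (SD, 8 h of light and 16 h of dark) for the whole dry period. Biopsies at day -24 and day -9 relative to calving gave 14 arrays: 3 from LD and 3 from SD at day -24, and 4 from LD and 4 from SD at day -9. Per the labels, RNA with an integrity number above 7.0 was used, and 2 µg of total RNA per sample was made into biotinylated cRNA with an oligo(dT) primer. The labels do not say whether the same cows gave both biopsies.

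The authors summarised the Affymetrix bovine arrays by robust multi-array average (RMA). The deposited values are on a log2 scale, 1 value per probe set and array. The software and its version are not stated. The table held 24128 probe sets without a missing value, between 1.49 and 14.0. Arrays have no read depth, and the number of arrays limits the precision. Signal was taken as deposited, with no background subtraction and no filter on low values.

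The 112 Affymetrix control probe sets were left out of the tests, which leaves 24016. Of these, 13292 carry 1 gene symbol in the array annotation, 86 carry several and 10638 carry none. The named probe sets cover 9155 genes. No genome was used here, so no positions are given.

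The tests per probe set, the tests of gene lists and the lists themselves were fixed before the data were examined. In R 4.3.3, limma 3.58.1 fitted the means of the 4 groups over all 14 arrays. The 7 contrasts were SD minus LD at day -24, at day -9 and averaged over days, day -9 minus day -24 in LD, in SD and averaged over photoperiods, and the difference between both day contrasts (the photoperiod by day interaction, SD minus LD). The moderated test was two-sided, without an intensity trend. Its p-values were adjusted by Benjamini-Hochberg over the 24016 probe sets, with a threshold of 0.05. Data of the same layout were simulated with 200 changed probe sets per contrast, for the 4 contrasts of group pairs. The procedure recovered between 53.5% and 72.0% of changes of 2-fold and between 91.0% and 95.0% of changes of 4-fold. Between 3 and 14 unchanged probe sets were called beside them. The simulated noise was normal and independent between probe sets, without arrays that stand apart. These shares therefore need not hold for the real arrays.

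Fixed gene lists, 34 in number with 667 measured genes and between 5 and 58 per list, were tested with camera of limma on 1 probe set per gene, that of the highest mean. The preset correlation between genes was 0.01, and p-values were adjusted over the 34 lists of a contrast. The test with a correlation estimated from the data was run beside it, and its adjusted p is given with each call. Lists covered milk proteins, lactose synthesis and glucose supply, milk fat synthesis, cholesterol synthesis, cell cycle and proliferation, prolactin and growth hormone signalling, the IGF axis, steroid hormone response, the circadian clock, serotonin and calcium homeostasis, involution and cell death, interferon response, innate defence and acute phase, antigen presentation class II and class I, the unfolded protein response and secretory pathway, and amino acid transport and synthesis. Further lists covered oxidative phosphorylation, fatty acid oxidation, ribosomal proteins, stress and immediate early genes, and growth factors and morphogenesis. Marker lists covered luminal epithelial, myoepithelial, adipocyte, fibroblast and matrix, endothelial, T and NK, B and plasma, macrophage and dendritic, neutrophil, skeletal muscle, erythrocyte and skin keratinocyte cells. Of the measured genes, 21 stand in more than 1 list. A list score is the mean over members of the value per array, centred on the mean of all arrays. Scores were compared between photoperiods, at each day and for the interaction, by two-sided exact permutation. For the interaction, photoperiods were permuted within each day, which is exact only if photoperiod has no effect at either day. This comparison of scores was not in the fixed plan.

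Named genes followed a fixed rule. Where fewer than 5 probe sets passed the threshold, the 10 genes of smallest unadjusted p were taken, and from each list up to 4 members of smallest p. PRLR, CSN2, LALBA, IGF1, ADIPOQ and KRT18 were always reported, each by its probe set of the highest mean. IGF1 has 4 probe sets and CSN2 has 3, and values of the others are not given here. STAT5A, MKI67 and PER1 were on the same list of genes and had no probe set under their symbol. The 3-prime and 5-prime control probe sets of 6 transcripts served as signs of RNA quality, compared by exact permutation. Actin, the dimmest of them, was left out of their mean. The fixed plan had named GAPDH and actin alone.

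Alternatives were filters on mean signal, other prior variances, centring or repeated quantile normalization, array weights, fits on 2 groups, other thresholds, 1 probe set per gene, the median over the probe sets of a gene, replicate number as a block, adipocyte or luminal marker means as covariates, 1 surrogate variable (the iteratively reweighted algorithm of the sva package, written out in R), and each array left out in turn. Leaving out 2 arrays together, in 2 versions, was added after the data had been seen. In a comparison of 2 groups, an array of another group enters only through the shared estimate of spread. Leaving out such an array keeps the median unchanged, so a call kept there is a weak check. The closing section gives the effect of the alternatives.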

Results

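Expression was measured in mammary biopsies of dry Holstein cows kept in long days (LD) or short days (SD), at day -24 and day -9 before calving. There were 3 arrays each of LD and SD at day -24 and 4 each at day -9. Every array gave log2 values for 24016 tested probe sets. Array medians lay between 6.43 and 6.61, and the Pearson correlation between pairs of arrays, across probe sets, between 0.950 and 0.992. Milk protein transcripts were abundant in the 4 groups: the beta-casein gene CSN2 had a log2 mean of 12.88 ± 0.22 in LD and 12.71 ± 0.15 in SD at day -24 (standard deviation, n = 3 each), and of 12.79 ± 0.15 in LD and 12.86 ± 0.14 in SD at day -9 (standard deviation, n = 4 each).

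Some arrays stood apart from the others of their group. LD day -24 replicate 1 lay at -62.6 on the first principal component, which held 25.2% of the variance, and SD day -9 replicate 1 lay at 53.9 on the third, with 13%. In LD day -9 replicate 4 and SD day -24 replicate 3, 280 probe sets were lower than in each of the other 12 arrays by at least 0.7, with a median difference of -1.41. Of these, 136 carry a single gene symbol, of 126 genes. The next pair of arrays shared 11 such probe sets. LD day -9 replicate 4 and SD day -24 replicate 3 are called the 2 arrays of low signal below, for those 280 probe sets alone. Their medians over all probe sets, 6.56 and 6.57, lay within the range of the other arrays. The 3-prime to 5-prime difference of GAPDH differed by -0.19 between day -9 and day -24 (exact permutation p = 0.0110 over 3003 arrangements, two-sided, 0.198 adjusted over 18 such tests). EIF4E differed by -0.47 (exact permutation p = 0.0716), EF1A and GST by -0.10 each, actin by -0.04 and cyclophilin by 0.02. The mean over 5 transcripts, without actin, was 0.98, 1.26 and 1.33 in SD at day -24 and 0.84 to 0.99 in SD at day -9. In LD it was 0.90 to 1.12 at day -24 and 0.80 to 1.21 at day -9. Whether RNA quality adds to the comparisons between days was not tested.

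**Figure D1:**
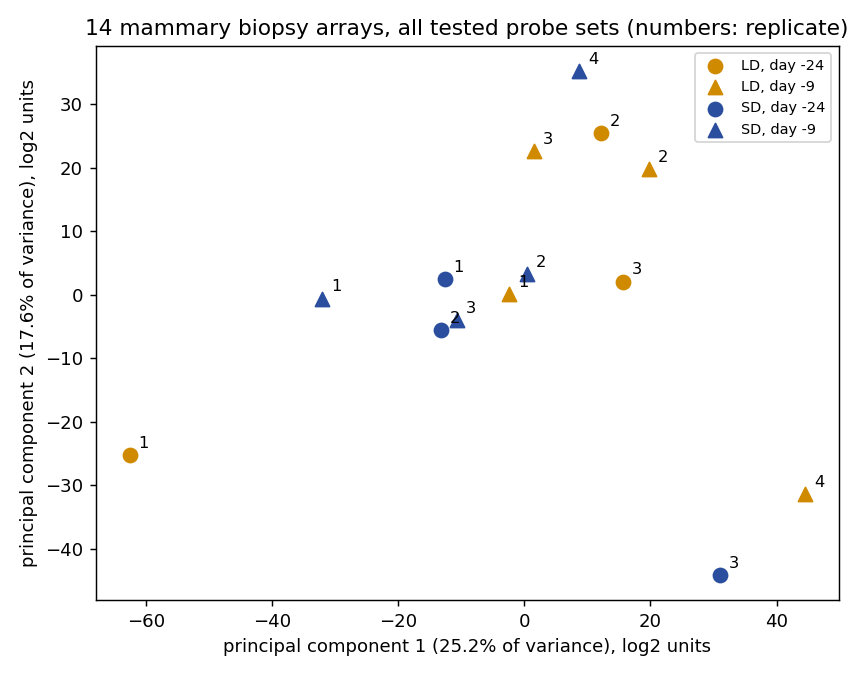
The 14 arrays on the first and second principal components of all tested probe sets (log2 units), coloured by photoperiod and shaped by day. LD day -24 replicate 1 lies far to the left at -62.6, and LD day -9 replicate 4 and SD day -24 replicate 3 lie low on the second component at -31.4 and -44.1.

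The comparison of SD with LD at day -24 asks what photoperiod changed in the gland early in its preparation for lactation. Cell cycle genes rose as a list in SD: 35 of 37 measured members were above 0, with a median log2 difference of 0.42 (camera adjusted p = 6.9e-05). With an estimated correlation, the adjusted p = 0.992. The mitotic kinase AURKA was at 7.36 ± 0.67 in SD against 6.49 ± 0.31 in LD (standard deviation, n = 3 each), a difference of 0.88. Genes of the unfolded protein response and secretory pathway, which fold and export proteins, fell as a list: 27 of 28 were below 0, with a median of -0.13 (adjusted p = 2.0e-07, and adjusted p = 0.362 with an estimated correlation). The chaperone genes CALR and HYOU1 differed by -0.81 and -0.45.

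Milk proteins at day -24 fell as a list, with 9 of 10 members below 0 and a median of -0.07 (camera adjusted p = 0.0485, and adjusted p = 0.988 with an estimated correlation). Of these, the alpha-S2-casein gene CSN1S2 differed by -0.61 and CSN2 by -0.16. The list median was -0.12 without LD day -24 replicate 2, -0.26 without LD day -24 replicate 3 and -0.26 without SD day -24 replicate 1. Stress and immediate early genes fell with a median of -0.06, with 19 of 28 below 0 (adjusted p = 0.0322, and adjusted p = 0.362 with an estimated correlation), and HSPA1A differed by -0.44 and ZFP36 by -0.34. Their median was -0.10 without LD day -24 replicate 2, -0.13 without LD day -24 replicate 1 and 0.00 without LD day -24 replicate 3. No member of these 4 lists passed 0.05, over all probe sets or adjusted over the list alone. Scores of the cell cycle list were 0.74, -0.24 and 0.72 in SD and between -0.23 and 0.19 in LD (exact permutation p = 0.400, where 3 against 3 arrays allow no p under 0.1). For the scores of the other 3 lists the exact permutation p was 0.3 (unfolded protein response), 0.6 (milk proteins) and 0.3 (stress genes), and 1 for each of the 4 adjusted over 34 lists.

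For single genes at day -24, limma called 0 probe sets past an adjusted p of 0.05, and 580 had an unadjusted p under 0.05 (284 higher, 296 lower) where chance gives 1201. The smallest p belonged to AGA, which encodes a lysosomal enzyme of glycoprotein breakdown, at 8.51 ± 0.16 in SD and 7.49 ± 0.25 in LD (standard deviation, n = 3 each). That is a 2.04-fold difference (log2 1.03, SE 0.18, limma adjusted p = 1). The other 9 genes of smallest p had values not past the threshold either: the hyaluronan synthase HAS2 -1.29, RPS6KL1 0.68, the RING finger gene LNX2 -0.64, EAF2 0.61, the imprinted gene PEG3 -0.60, ZP2 0.59, ARHGAP31 0.59, the matrix protease MMP14 -0.45 and EXO5 0.44. For RPS6KL1 the second probe set, and for HAS2 1 of the 2 others, had the opposite sign. MMP14 and ZP2 had low signal, with group means of 4.22 or below, under the lower quartile of every array (4.47 or above). PRLR, the prolactin receptor, differed by -0.58 (95% interval -1.46 to 0.30) and IGF1 by -0.68 (-1.88 to 0.51). Both probe sets are among the 280 that were low in SD day -24 replicate 3 and LD day -9 replicate 4, and without these arrays the differences were -0.16 and -0.11. LALBA, ADIPOQ and KRT18 differed by -0.06, -0.12 and 0.08.

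The cell cycle call at day -24 ended without SD day -24 replicate 1 (0.30, adjusted p = 0.182). Without SD day -24 replicate 2 the cell cycle median was 0.80. The call of the unfolded protein response list stayed in all 14 refits. Its median was -0.08 without SD day -24 replicate 2 and -0.20 without SD day -24 replicate 1. Refits without a day -9 array leave the medians of this comparison unchanged. Milk proteins were at 0.05 (adjusted p = 0.719) without LD day -24 replicate 1. They lost their call without each of 6 further arrays (adjusted p between 0.0502 and 0.333), some of them day -9 arrays. With the adipocyte or luminal marker mean as a covariate their call ended too (medians 0.02 and -0.08, adjusted p = 0.592 and 0.0560). Stress genes lost theirs without 4 arrays (0.0694 to 0.221).

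**Figure D2:**
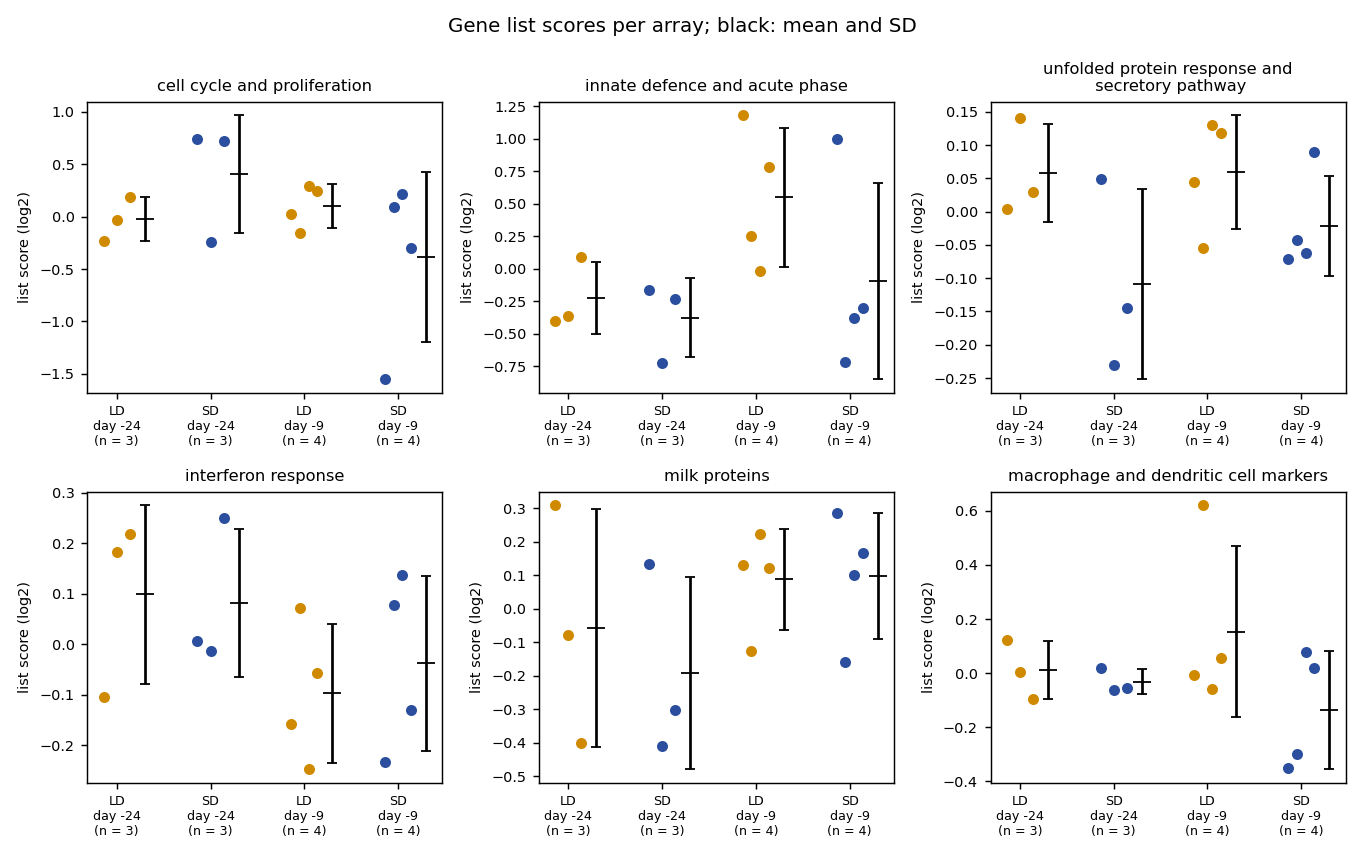
Scores of 6 gene lists (mean over members, log2, centred over all arrays) for each array, by photoperiod and day, with mean and standard deviation in black. The cell cycle score of SD day -9 replicate 1 was -1.55, and the macrophage score of LD day -9 replicate 2 was 0.62, each apart from the others of its group.

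At day -9 the same contrast asks what photoperiod changed close to calving. Innate defence and acute phase genes fell as a list in SD, with 29 of 32 members below 0 and a median of -0.58 (camera adjusted p = 1.6e-06, and adjusted p = 0.731 with an estimated correlation). The antimicrobial defensin gene DEFB4A was at 6.85 ± 1.37 in SD against 9.38 ± 1.11 in LD (standard deviation, n = 4 each), a 5.79-fold difference. Of this list, 7 members had an unadjusted p under 0.05, all lower in SD. Adjusted over the list alone, 2 passed, DEFB4A (-2.53, 0.0414) and the acute phase gene ORM1 (-0.87, 0.0414), and over all probe sets 0 passed. The neutrophil attractants CXCL5 and CXCL8 differed by -1.10 and -0.92.

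Macrophage and dendritic cell markers fell with it: 20 of 22 were below 0, with a median of -0.22 (adjusted p = 0.000272, and adjusted p = 0.839 with an estimated correlation). GPNMB, a glycoprotein of macrophages, was at 6.70 ± 0.59 in SD against 8.20 ± 0.23 in LD, and the lysosomal macrophage marker CD68 at 7.06 ± 0.36 against 8.17 ± 0.49 (standard deviation, n = 4 each). These 2 members passed when adjusted over the list alone (0.0117 each), and 0 passed over all probe sets. Neutrophil markers fell with a median of -0.33 (14 of 17 below 0, adjusted p = 0.0118, and adjusted p = 0.855 with an estimated correlation), and S100A8 differed by -1.41. S100A8, LTF and CATHL1 stand in both this list and the innate defence list, so calls of these lists are not independent in any comparison. The neutrophil median was -0.13 without LD day -9 replicate 1, -0.54 without LD day -9 replicate 3 and -0.67 without SD day -9 replicate 1, and that of macrophage markers -0.11 without SD day -9 replicate 1. Fibroblast and matrix markers fell with a median of -0.24 (23 of 30 below 0; adjusted p = 0.00524, and adjusted p = 0.855 with an estimated correlation), among them PDGFRA at -0.46 and the proteoglycan DCN at -0.42, and were at -0.38 without LD day -9 replicate 4. Endothelial markers rose by 0.11 (13 of 18 above 0; adjusted p = 0.0382, and adjusted p = 0.855 with an estimated correlation), with 0.02 without LD day -9 replicate 2 and 0.18 without SD day -9 replicate 4.

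Cell cycle genes at day -9 fell as a list in SD, opposite in sign to day -24: 35 of 37 were below 0, with a median of -0.52 (camera adjusted p = 7.5e-07, and adjusted p = 0.855 with an estimated correlation). The spindle checkpoint gene MAD2L1 differed by -1.04 and CENPF by -0.95. Scores were -1.55, 0.09, 0.22 and -0.30 in SD and between -0.16 and 0.30 in LD (exact permutation p = 0.286). Oxidative phosphorylation fell with a median of -0.12 (42 of 44 below 0; adjusted p = 0.000357, and adjusted p = 0.855 with an estimated correlation), or -0.07 without LD day -9 replicate 4. Fatty acid oxidation fell with a median of -0.18 (16 of 20 below 0; adjusted p = 0.00992, and adjusted p = 0.731 with an estimated correlation), with the enzyme gene ECI1 at -0.44. Circadian clock genes rose by 0.22 (7 of 10 above 0; adjusted p = 0.00992, and adjusted p = 0.319 with an estimated correlation). Among them PER2, a repressor in the clock, was at 8.26 ± 0.33 in SD and 7.78 ± 0.21 in LD (standard deviation, n = 4 each). None of the members of these 4 lists, or of the neutrophil, fibroblast and endothelial lists, passed when adjusted over the list alone (0 by limma).

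By the scores of the arrays, none of the 9 lists was past 0.05 at day -9. The exact permutation p was 0.2 for innate defence and neutrophil markers, 0.257 for macrophage markers and oxidative phosphorylation, and 0.0857 for the circadian clock. It was 0.143 for fatty acid oxidation, 0.429 for fibroblast and 0.6 for endothelial markers. Adjusted over 34 lists it was 0.863 or more in each.

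Among single genes at day -9, limma called 0 probe sets past the threshold, and 666 had an unadjusted p under 0.05 (346 higher, 320 lower; chance gives 1201). The potassium channel subunit gene KCNE4 had the smallest p, at 7.02 ± 0.30 in SD and 8.15 ± 0.25 in LD (standard deviation, n = 4 each; log2 difference -1.13, SE 0.21, limma adjusted p = 0.984). Besides GPNMB, CD68 and DEFB4A, the genes of smallest p were PLA2G7 (-0.84), an enzyme that inactivates platelet-activating factor, ABO (-0.83), AGA (0.66), SYT17 (-0.65), APOM (-0.61) and PPM1K (-0.50). The 3 other probe sets of PPM1K and the second of AGA had the opposite sign. SYT17 had low signal, with group means of 3.75 to 4.40. PRLR differed by 0.45 (-0.31 to 1.21), or 0.09 without LD day -9 replicate 4 and SD day -24 replicate 3, and IGF1 by -0.03 (-1.07 to 1.0), or -0.55 without them. CSN2, LALBA, ADIPOQ and KRT18 differed by 0.07, 0.04, -0.27 and 0.00.

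At day -9 the innate defence call stayed in all 14 refits, with medians of -0.91 without SD day -9 replicate 1 and -0.37 without SD day -9 replicate 2. Without SD day -9 replicate 1 the calls of the cell cycle (-0.13, adjusted p = 0.751) and oxidative phosphorylation (0.184) ended, without LD day -9 replicate 2 that of macrophage markers (-0.03, 0.581), and without LD day -9 replicate 3 that of fibroblast markers (-0.05, 0.916), which also ended without LD day -9 replicate 1 (0.0637) or SD day -9 replicate 1 (0.0952), and each of the remaining calls ended without 2 to 6 of the arrays (0.0521 to 0.482), that of neutrophil markers also with the adipocyte marker mean as a covariate (-0.30, 0.0565).

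Averaged over both days, SD against LD gives the mean of the photoperiod differences at day -24 and day -9, which need not be alike. Innate defence genes fell with a median of -0.29 (29 of 32 below 0) and genes of the unfolded protein response and secretory pathway with -0.12 (27 of 28 below 0). Both had a camera adjusted p = 2.4e-09, and an adjusted p = 0.405 with an estimated correlation. DEFB4A differed by -1.78, IL1B by -0.37, HYOU1 by -0.34 and the translocon gene SEC61A1 by -0.25. Macrophage markers fell with a median of -0.09 (16 of 22 below 0; adjusted p = 4.1e-05, and adjusted p = 0.598 with an estimated correlation), neutrophil markers with -0.16 (12 of 17; adjusted p = 0.0144, and adjusted p = 0.752 with an estimated correlation) and fibroblast markers with -0.10 (24 of 30; adjusted p = 0.00908, and adjusted p = 0.765 with an estimated correlation). Endothelial markers rose by 0.11 (17 of 18 above 0; adjusted p = 0.00495, and adjusted p = 0.659 with an estimated correlation).

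Single arrays moved the smaller of these medians. That of macrophage markers was -0.04 without SD day -9 replicate 1, -0.14 without LD day -24 replicate 3 or SD day -9 replicate 3, and -0.15 without LD day -9 replicate 1. The neutrophil median was -0.03 without LD day -24 replicate 1 and -0.29 without LD day -9 replicate 2. Fibroblast markers were at -0.22 without LD day -24 replicate 1, -0.16 without LD day -9 replicate 2, -0.19 without LD day -9 replicate 4, -0.18 without SD day -24 replicate 2 and -0.02 without LD day -9 replicate 3. Endothelial markers were at 0.03 without SD day -24 replicate 3, 0.18 without each of LD day -24 replicate 2, LD day -9 replicate 3 and SD day -24 replicate 2, and 0.19 without SD day -9 replicate 4. In these 6 lists, 0 members passed adjusted over the list alone.

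By day, innate defence genes had a median of -0.03 at day -24 (19 of 32 below 0, camera adjusted p = 0.0577) and -0.58 at day -9, and fibroblast markers 0.02 (16 of 30 above 0) and -0.24. Macrophage markers were at -0.06 and -0.22, neutrophil markers at -0.03 and -0.33 and endothelial markers at 0.14 and 0.11. The unfolded protein response list was at -0.13 at day -24 and -0.06 at day -9 (adjusted p = 0.154). None of the 6 lists was past the threshold at both days, and none was past it in the interaction (smallest adjusted p = 0.0542, unfolded protein response).

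AGA was the single gene of smallest p in this average, 1.80-fold higher in SD (log2 0.84, SE 0.12, limma adjusted p = 0.150). Its 7 SD arrays lay at 7.97 or above and its 7 LD arrays at 7.79 or below. The second AGA probe set differed by 0.14 (95% interval -0.21 to 0.50), and the first passed the threshold without SD day -9 replicate 3 (0.92, adjusted p = 0.0177). No probe set passed the threshold in limma, and 467 had an unadjusted p under 0.05 (248 higher, 219 lower; chance gives 1201). The other genes of smallest p were the trypsin gene PRSS2 (3.2), PEBP4 (-1.72), TMEM183A (-0.97, with the same sign in 1 of its 3 other probe sets), GPNMB (-0.95), the iron reductase STEAP3 (0.68), ABO (-0.53, with the opposite sign in its 2 other probe sets), KIR3DS1 (-0.48), the zinc finger gene ZNF184 (0.40) and PEG3 (-0.38), none past the threshold. PRSS2 was at 8.34 or above in 5 of 7 SD arrays and at 5.91 or below in the other 2 and in all LD arrays. KIR3DS1 had low signal, with group means of 2.83 to 3.34. PRLR, CSN2, LALBA, IGF1, ADIPOQ and KRT18 differed by -0.07, -0.05, -0.01, -0.36, -0.19 and 0.04.

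The innate defence and unfolded protein response calls of the average stayed in all 14 refits, the latter at -0.07 without SD day -24 replicate 2. Macrophage markers lost their call without LD day -24 replicate 1 (-0.06, adjusted p = 0.0819) and without LD day -9 replicate 2 (-0.01, 0.0941), and turned to 0.02 (0.285) without both LD day -24 replicate 1 and SD day -9 replicate 1, and the neutrophil, fibroblast and endothelial calls each ended without 5 to 7 of the arrays (0.0579 to 0.777), the neutrophil call also with the adipocyte covariate (-0.13, 0.272).

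**Figure D3:**
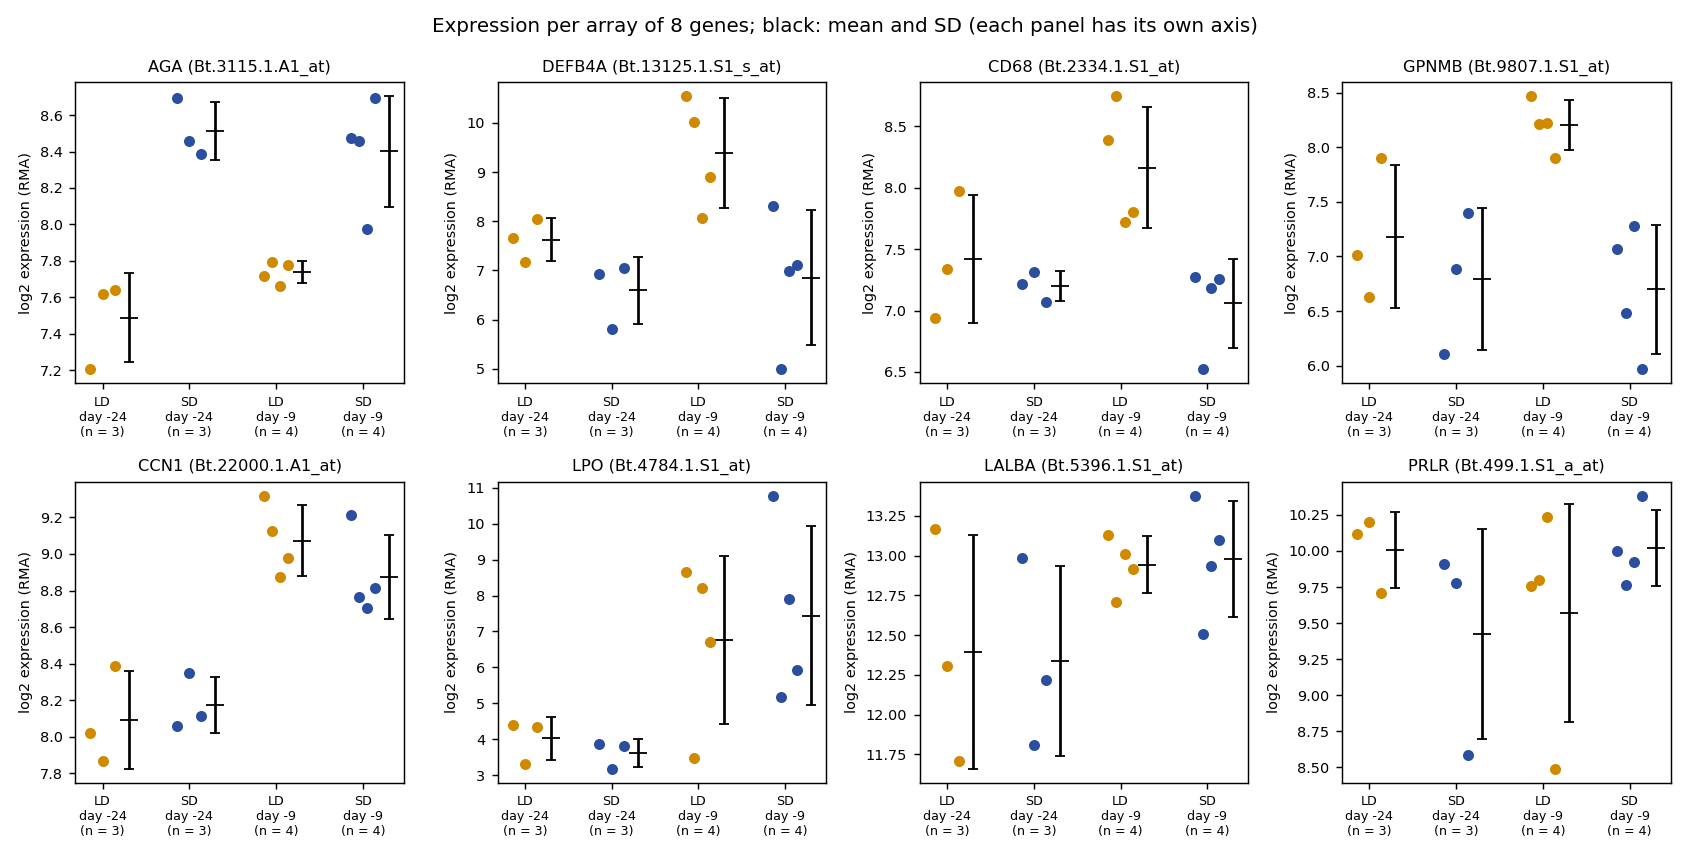
Log2 expression of 8 genes in each array, by photoperiod and day, with mean and standard deviation in black and a separate axis per panel. The 7 SD arrays lie above the 7 LD arrays for AGA, and PRLR is lowest in LD day -9 replicate 4 (8.49) and SD day -24 replicate 3 (8.59).

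In LD cows, day -9 against day -24 asks how the gland changed as calving came near. Innate defence genes rose as a list, with 27 of 32 members above 0, a median of 0.73 and 9 members at an unadjusted p under 0.05 (camera adjusted p = 0.000306, and adjusted p = 0.716 with an estimated correlation). The antimicrobial peptide gene LAP differed by 2.44, the ferroxidase CP by 1.65 and the cytokine IL6 by 0.96. With the luminal marker mean as a covariate the list median was 0.37 (adjusted p = 0.0141). Interferon response genes fell, 18 of 23 below 0 with a median of -0.15 (adjusted p = 0.000601, and adjusted p = 0.716 with an estimated correlation). The interferon-induced genes MX1 and RSAD2 differed by -0.58 and -0.57, and HERC6 by -0.45.

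Lactose synthesis and glucose supply rose in LD by a median of 0.29, with 9 of 9 members above 0 (adjusted p = 0.0380, and adjusted p = 0.716 with an estimated correlation). PGM1 differed by 0.37, the glucose transporter SLC2A1 by 0.32 and LALBA, the alpha-lactalbumin subunit of lactose synthase, by 0.55. Oxidative phosphorylation rose by 0.14 (41 of 44 above 0; adjusted p = 0.00485, and adjusted p = 0.997 with an estimated correlation) and fatty acid oxidation by 0.20 (18 of 20; adjusted p = 0.0368, and adjusted p = 0.716 with an estimated correlation), the latter at 0.10 without LD day -24 replicate 1 and 0.37 without LD day -24 replicate 3. Involution and cell death genes rose by 0.27 (19 of 26; adjusted p = 0.0368, and adjusted p = 0.716 with an estimated correlation), or 0.16 without LD day -24 replicate 1. Their members of smallest p were BAX, which promotes apoptosis (0.78), TIMP1, which inhibits metalloproteases (0.80), and BCL2L1, whose long form opposes apoptosis (0.32). Adjusted over the list alone, BAX (0.0135) and HERC6 (0.0130) passed in their lists, no member of the other 4 lists did, and over all probe sets 0 passed. The signal of HERC6 was low, with LD means of 3.79 at day -9 and 4.24 at day -24.

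Single genes in LD gave 0 probe sets past the threshold in limma and 1795 at an unadjusted p under 0.05 (867 higher, 928 lower; chance gives 1201). CCN1, a matrix-associated signalling protein, was at 9.07 ± 0.19 at day -9 (standard deviation, n = 4) and 8.09 ± 0.27 at day -24 (standard deviation, n = 3), a log2 difference of 0.98 (SE 0.16, limma adjusted p = 0.478). KCNE4 differed by 1.31 (SE 0.22, limma adjusted p = 0.478). Further genes of smallest p, none past the threshold, were the phosphatase DUSP1 (0.75), the neuropeptide NMB (0.74), PPM1K (0.60), the folate hydrolase GGH (-0.53), NKIRAS1 (0.50) and SLC7A6OS (0.44), besides BAX and HERC6. Of the 3 other PPM1K probe sets, 2 had the opposite sign. PRLR differed by -0.44 (-0.08 without the 2 arrays of low signal), IGF1 by -0.33 (0.18 without them), CSN2 by -0.09, ADIPOQ by 0.17 and KRT18 by -0.07.

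The innate defence and interferon calls in LD stayed in all 14 refits, the latter at -0.26 without LD day -9 replicate 2. Oxidative phosphorylation lost its call without LD day -24 replicate 3 (0.14, adjusted p = 0.0560) and was at 0.09 without LD day -24 replicate 1, and the lactose, involution and fatty acid oxidation calls each ended without 4 or 5 of the arrays (0.0547 to 0.256), and with the luminal (0.0564, 0.156 and 0.10) or adipocyte marker mean as a covariate (0.335, 0.260 and 0.147).

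In SD cows, the same days gave the largest list shift among the comparisons of 2 groups. Cell cycle genes fell from day -24 to day -9: 37 of 37 members were below 0, 18 of them at an unadjusted p under 0.05, with a median of -0.85 (camera adjusted p = 3.8e-19, and adjusted p = 0.492 with an estimated correlation). The cyclin gene CCNE2 was at 5.42 ± 0.69 at day -9 (standard deviation, n = 4) and 6.51 ± 0.25 at day -24 (standard deviation, n = 3), and the kinase MELK differed by -1.18. Milk proteins rose, 10 of 10 members above 0 with a median of 0.19 (adjusted p = 0.00485, and adjusted p = 0.492 with an estimated correlation). With the adipocyte marker mean as a covariate the median turned to -0.04 (adjusted p = 0.763), and adipocyte markers rose in the same comparison. The milk protein median was 0.34 without SD day -24 replicate 1 and 0.07 without SD day -24 replicate 2. GLYCAM1 differed by 0.79, LALBA by 0.64, CSN1S2 by 0.61 and CSN2 by 0.14.

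Milk fat synthesis rose in SD by 0.12 (21 of 26 above 0; adjusted p = 0.0135, and adjusted p = 0.492 with an estimated correlation). With the adipocyte covariate it turned to -0.04 (adjusted p = 0.606), and without SD day -24 replicate 2 to -0.03 (0.344), while it was 0.08 without SD day -9 replicate 1 and 0.21 without SD day -9 replicate 2. FABP3 differed by 0.87 and VLDLR by 0.55, while the citrate lyase ACLY was at -0.28. Innate defence genes rose by 0.28 (24 of 32; adjusted p = 0.0135, and adjusted p = 0.575 with an estimated correlation): the peroxidase gene LPO was at 7.44 ± 2.50 at day -9 (standard deviation, n = 4) and 3.61 ± 0.39 at day -24 (standard deviation, n = 3), and LBP differed by 1.47. That call ended with the luminal marker mean as a covariate (median -0.07, adjusted p = 0.60) and with the adipocyte one (0.17, 0.376), and both marker lists rose in the same comparison. Without SD day -24 replicate 2 it ended as well (0.11, 0.0787). Neutrophil markers fell with a median of -0.29 (11 of 17 below 0; adjusted p = 0.0309, and adjusted p = 0.575 with an estimated correlation), with the cathelicidin gene CATHL3 at -1.16, and were at -0.12 without SD day -24 replicate 1. Antigen presentation class II fell with a median of -0.20 (10 of 12, adjusted p = 0.0496, and adjusted p = 0.492 with an estimated correlation), with BOLA-DOA at -0.51, and was at -0.12 without SD day -24 replicate 2. With replicate number as a fixed block the class II call ended (camera adjusted p = 0.109).

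Markers of several cell types rose together in SD. Luminal epithelial markers rose by 0.16 (15 of 20 above 0) and myoepithelial markers by 0.19 (11 of 14), each with an adjusted p = 0.0135, and adipocyte markers by 0.21 (13 of 18; adjusted p = 0.0219). For these 3 lists the adjusted p = 0.492 with an estimated correlation. KRT19 differed by 0.30, KRT17 by 0.53 and FABP4 by 0.53, while the receptor gene KIT was at -0.61. Luminal markers were at 0.07 without SD day -24 replicate 2 and 0.06 without SD day -9 replicate 1, myoepithelial markers at 0.03 without SD day -9 replicate 1, and adipocyte markers at 0.12 without SD day -24 replicate 1 and 0.07 without SD day -9 replicate 3. Endothelial markers rose by 0.12 (14 of 18; adjusted p = 0.0434, and adjusted p = 0.575 with an estimated correlation), with 0.02 without SD day -24 replicate 2, 0.07 without SD day -9 replicate 1 and 0.23 without SD day -24 replicate 3. Involution and cell death genes rose by 0.14 (19 of 26; adjusted p = 0.0135) and stress and immediate early genes by 0.10 (19 of 28; adjusted p = 0.0272). Both had an adjusted p = 0.492 with an estimated correlation, and IGFBP5 differed by 0.61 and ZFP36 by 0.56. The stress list turned to -0.02 without SD day -9 replicate 2 (adjusted p = 0.147), and was at 0.05 without SD day -9 replicate 1, 0.16 without SD day -9 replicate 4, 0.18 without SD day -24 replicate 3 and 0.04 with the luminal covariate, and involution genes were at 0.02 without SD day -9 replicate 1. The unfolded protein response and secretory pathway rose by 0.03 (18 of 28; adjusted p = 0.0496, and adjusted p = 0.575 with an estimated correlation), with the stress kinase EIF2AK3 at 0.76. Its median was 0.11 without SD day -24 replicate 1, 0.05 without SD day -9 replicate 1, 0.02 without SD day -24 replicate 2 or SD day -9 replicate 3, 0.01 without SD day -9 replicate 2 and 0.00 without SD day -9 replicate 4. Its call ended with replicate number as a fixed block (camera adjusted p = 0.174) and with photoperiod and number as a random block (0.0567). Of the 13 lists, 0 members passed adjusted over the list alone.

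Single genes in SD gave 0 probe sets past the threshold in limma and 1096 at an unadjusted p under 0.05 (632 higher, 464 lower; chance gives 1201). The semaphorin receptor PLXNB2 was at 5.62 ± 0.19 at day -9 (standard deviation, n = 4) and 4.73 ± 0.22 at day -24 (standard deviation, n = 3), a log2 difference of 0.89 (SE 0.16, limma adjusted p = 0.970). The other genes of smallest p were BPI (-1.06), an antibacterial protein of neutrophils, CCN1 (0.70), the spindle gene KNSTRN (-0.67), the calcium channel ORAI1 (0.65), the deubiquitinase USP4 (0.63), VPS39 (0.62), RAPGEF1 (0.54), the ubiquitin ligase subunit CUL1 (0.50) and the apoptosis inhibitor XIAP (0.39), none past the threshold. XIAP had low signal, with group means of 3.08 to 3.47. A probe set with no gene symbol passed the threshold without SD day -24 replicate 3 (-2.29, adjusted p = 0.0277). PRLR differed by 0.59 (0.17 without the 2 arrays of low signal), IGF1 by 0.32 (-0.26 without them), ADIPOQ by 0.02 and KRT18 by -0.14.

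SD day -9 replicate 1 weighed on most calls in SD: without it 2 of the lists stayed past the threshold, innate defence turned to -0.01 (adjusted p = 0.983), and the cell cycle list, which kept its call in all 14 refits, was at -0.42. The other 12 calls each ended without 2 to 10 of the arrays (adjusted p between 0.0501 and 0.983). For class II and the unfolded protein response, some of these were LD arrays, whose omission leaves the medians in SD unchanged. With either marker covariate, the calls of involution, class II, the unfolded protein response, myoepithelial and endothelial markers ended too. The adjusted p was 0.0609 to 0.719 with the luminal covariate and 0.0714 to 0.631 with the adipocyte one, where endothelial markers turned to -0.05.

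Averaged over photoperiods, day -9 against day -24 gives the mean of the changes in LD and SD, which need not be alike. Cell cycle genes fell in this mean, 36 of 37 below 0 with a median of -0.35 (camera adjusted p = 1.2e-07, and adjusted p = 0.756 with an estimated correlation), among them the replication factor PCNA at -0.48. In LD alone the median was 0.16 (27 of 37 above 0, camera adjusted p = 0.967) and in SD -0.85. The interaction of the list had an adjusted p = 1.1e-08, and adjusted p = 0.762 with an estimated correlation, and its score an exact permutation p = 0.107, so a difference between LD and SD stays open. Innate defence genes rose, 29 of 32 above 0 with a median of 0.35 (adjusted p = 8.6e-06, and adjusted p = 0.581 with an estimated correlation): LPO differed by 3.28, LBP by 1.45, IL6 by 0.64 and the receptor TLR4 by 0.30. Their median was 0.18 with the luminal covariate (adjusted p = 0.0437) and 0.55 with probe sets of a mean of at least 5. Interferon response genes fell with a median of -0.17 (20 of 23 below 0; adjusted p = 0.000267, and adjusted p = 0.581 with an estimated correlation). Adjusted over the list alone, HERC6 (-0.28, 0.0326) and USP18 (-0.39, 0.0415) passed in that list, and over all probe sets 0 passed. The signal of HERC6 was low: its group means lay between 3.79 and 4.24, under the lower quartile of every array (4.47 or above).

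Lactose synthesis and glucose supply rose in this average by 0.21 (9 of 9 above 0; adjusted p = 0.0122), involution and cell death genes by 0.15 (23 of 26; adjusted p = 0.00118) and myoepithelial markers by 0.25 (11 of 14; adjusted p = 0.0108), while antigen presentation class II fell with a median of -0.22 (10 of 12; adjusted p = 0.00847). For these 4 lists the adjusted p = 0.581 with an estimated correlation. Luminal epithelial markers rose by 0.21 (16 of 20; adjusted p = 0.0162, and adjusted p = 0.659 with an estimated correlation). LALBA differed by 0.59 (95% interval 0.09 to 1.1; limma adjusted p = 0.636), BAX by 0.46, the smooth muscle actin gene ACTA2 by 0.35 and KRT19 by 0.31, while KIT was at -0.44. Without LD day -24 replicate 1 the lactose median was 0.13, the myoepithelial one 0.16 and the luminal one 0.07, and without SD day -9 replicate 1 the last 2 were 0.12 and 0.11. Adjusted over the list alone, 0 members of the 7 lists other than interferon response passed. Of the 8 lists, innate defence and involution were past the threshold in both LD and SD, lactose synthesis and interferon response in LD (in SD adjusted p = 0.112 and 0.0826), and class II, luminal and myoepithelial markers and the cell cycle were past it in SD (in LD 0.0502, 0.340, 0.266 and 0.967), with the cell cycle as the one of these lists past it in the interaction. Adipocyte markers had a median of 0.21 in this average (adjusted p = 0.0869).

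CCN1 had the smallest p of this average, 1.79-fold higher at day -9 (log2 0.84, SE 0.12, limma adjusted p = 0.157). Limma called 0 probe sets, and 1853 had an unadjusted p under 0.05 (873 higher, 980 lower; chance gives 1201). DUSP1 (0.64), PLXNB2 (0.53), RPL19 (-0.48), CELA1 (-0.47), COL26A1 (-0.42), USP4 (0.40), the splicing factors PNN (-0.37) and HNRNPH2 (-0.30), and CAMLG (-0.30) followed, none past the threshold. The second probe set of RPL19 differed by 0.00 and that of CAMLG by 0.17. PRLR, CSN2, IGF1, ADIPOQ and KRT18 differed by 0.08, 0.03, -0.01, 0.09 and -0.11.

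With the luminal marker mean as a covariate the calls of the cell cycle (-0.06, adjusted p = 0.191), involution (0.0541), lactose (0.0640), class II (0.396) and myoepithelial markers (0.484) ended, and with the adipocyte one those of involution (0.187), interferon (-0.06, 0.0673), lactose (0.427), luminal (0.0804) and myoepithelial markers (0.230). The cell cycle, innate defence, interferon and involution calls stayed in all 14 refits, with the cell cycle at -0.12 without SD day -9 replicate 1 and interferon at -0.10 without SD day -24 replicate 3, while the lactose call ended without SD day -24 replicate 2 (0.12, adjusted p = 0.0685), class II without LD day -24 replicate 1 (0.0736), myoepithelial markers without SD day -9 replicate 1 (0.0664), and luminal markers without LD day -24 replicate 1, SD day -24 replicate 3 or SD day -9 replicate 1 (0.134, 0.0751 and 0.150).

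The photoperiod by day interaction asks whether the change from day -24 to day -9 differed between SD and LD. Cell cycle genes had a lower change in SD: 35 of 37 members were below 0, 7 at an unadjusted p under 0.05, with a median of -0.97 (camera adjusted p = 1.1e-08, and adjusted p = 0.762 with an estimated correlation). AURKA differed by -1.32, CENPF by -1.71, ASPM by -1.64 and CCNB2 by -1.48. Oxidative phosphorylation fell in SD relative to LD with a median of -0.22 (43 of 44 below 0; adjusted p = 0.000480, and adjusted p = 0.762 with an estimated correlation), with NDUFS3 at -0.44. The median was -0.14 without LD day -24 replicate 1 or SD day -24 replicate 3, -0.33 without SD day -24 replicate 2 and -0.10 without the 2 arrays of low signal. Stress and immediate early genes rose by 0.11 (20 of 28 above 0; adjusted p = 0.0170, and adjusted p = 0.762 with an estimated correlation), with KLF4 at 0.63 and MYC at 1.14, and were at 0.03 without LD day -24 replicate 3 and 0.02 without SD day -9 replicate 2. The MYC probe set is among those low in LD day -9 replicate 4 and SD day -24 replicate 3, which both add to the interaction with the same sign. In these 3 lists, 0 members passed adjusted over the list alone. The exact permutation p of their scores was 0.107, 0.167 and 0.0900, or 0.901 each adjusted over 34 lists.

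Limma called 0 probe sets for the interaction, and 997 had an unadjusted p under 0.05 (599 higher, 398 lower; chance gives 1201). EXO5, a DNA exonuclease, had the smallest p (log2 -0.82, SE 0.16, limma adjusted p = 0.900). The next genes, none past the threshold, were the differentiation inhibitor ID2 (1.5), BPI (-1.45), KCNE4 (-1.35), the polycomb gene EED (-1.35), KNSTRN (-1.05), MYNN (0.98), EAF2 (-0.89), MMP14 (0.70) and the phosphatase PTPN2 (0.65). Of the 22 other EED probe sets, 12 had the same sign, as did 1 of 2 for MMP14 and 1 of 2 for PTPN2. MMP14 had low signal, with group means of 3.77 to 4.22. PRLR was at 1.03 (-0.13 to 2.19) and IGF1 at 0.65, and without the 2 arrays of low signal at 0.25 and -0.44. CSN2, LALBA, ADIPOQ and KRT18 were at 0.24, 0.09, -0.15 and -0.07.

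The cell cycle interaction kept its call in all 14 refits and had a median of -0.52 without SD day -9 replicate 1. Oxidative phosphorylation lost it without SD day -24 replicate 1 (-0.17, adjusted p = 0.0591), and stress genes without LD day -24 replicate 3, SD day -24 replicate 1 or SD day -9 replicate 2 (0.107, 0.0591 and 0.0674).

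**Figure D4:**
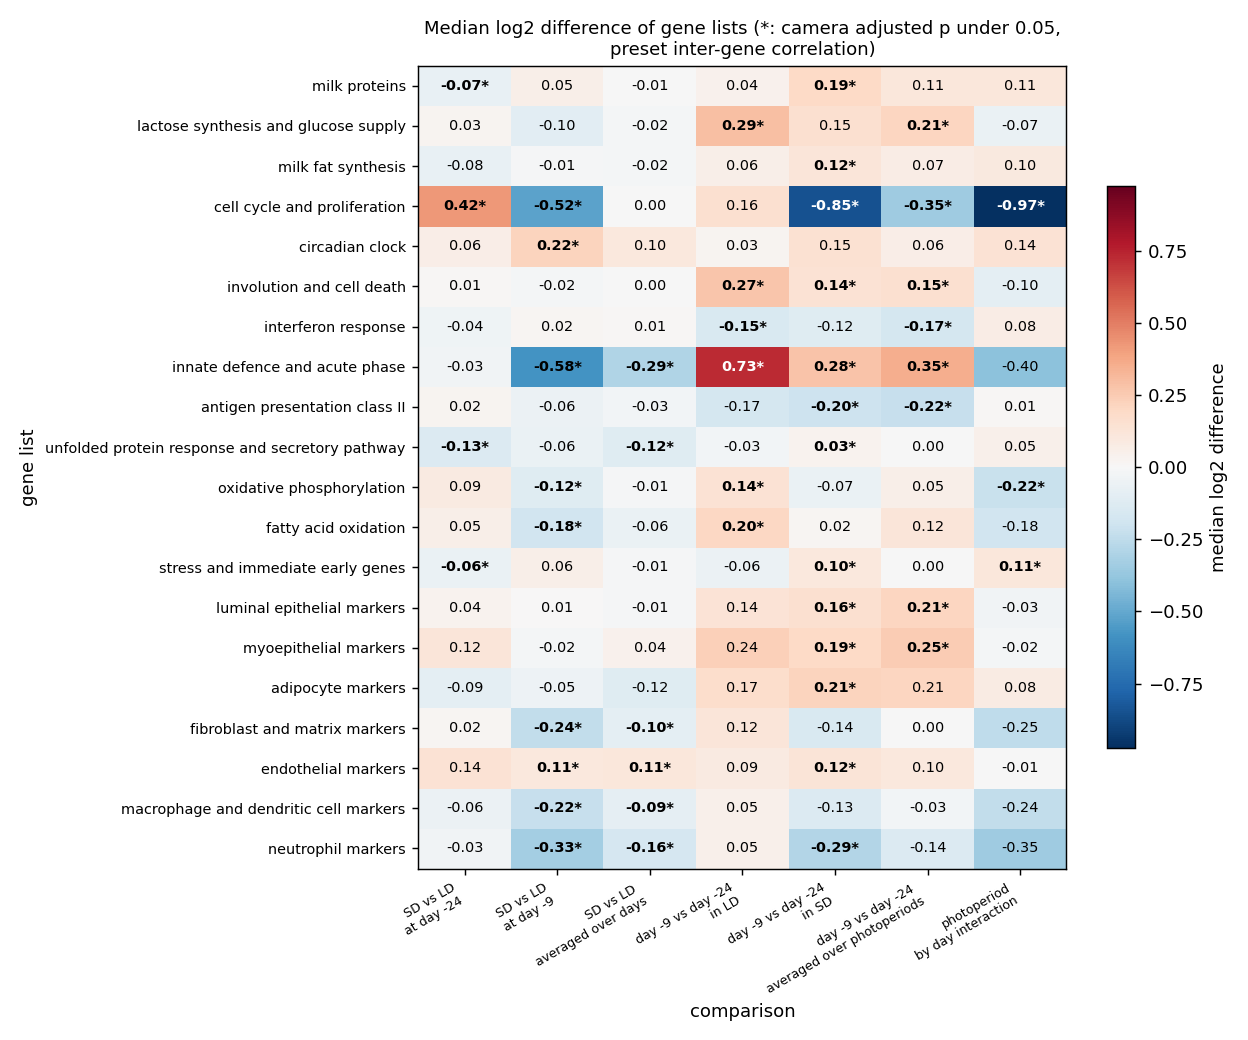
Median log2 difference of the 20 gene lists past the threshold in at least 1 comparison, for 7 comparisons (columns); asterisks mark a camera adjusted p under 0.05 with the preset correlation. Cell cycle genes stand at 0.42 at day -24 and -0.52 at day -9 for SD against LD, and no call held with an estimated correlation.

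Of the 34 lists, 14 were past the threshold in none of the 7 comparisons. Their smallest adjusted p was 0.0621, for prolactin and growth hormone signalling between days in SD (median 0.14). For the others the smallest adjusted p was 0.0700 for erythrocyte markers, 0.0770 for steroid hormone response, 0.0880 for ribosomal proteins, 0.104 for T and NK cell markers and 0.117 for skin keratinocyte markers. It was 0.228 for growth factors and morphogenesis, 0.238 for amino acid transport and synthesis, 0.269 for cholesterol synthesis, 0.271 for the IGF axis and 0.329 for B and plasma cell markers. It was 0.442 for serotonin and calcium homeostasis, 0.536 for skeletal muscle markers and 0.724 for antigen presentation class I. In all 49 calls, the median, the mean and the test had the same sign.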

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

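The tests that leave out SD day -9 replicate 1, use the luminal covariate or permute the cell cycle score, the 3-prime to 5-prime tests, the test of other probe sets outside the low set and the test of the second AGA probe set were chosen after the result had been seen. Refits without 1 array and with the luminal covariate were planned as alternatives, and only their use as tests of the cell cycle pattern came later. The splits of the arrays and the test of other probe sets of the same genes were planned before their results were seen.

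The change from day -24 to day -9 differed between SD and LD in 3 gene lists by the interaction test: cell cycle and proliferation (median -0.97), oxidative phosphorylation (-0.22) and stress and immediate early genes (0.11), all with the preset correlation and none with an estimated one (adjusted p = 0.762 for each). The cell cycle list was higher in SD at day -24 and lower at day -9. At day -9 this shift rests on SD day -9 replicate 1, without which its adjusted p was 0.751, and at day -24 on SD day -24 replicate 1, without which it was 0.182. With the preset correlation, the interaction call was kept without either array (camera adjusted p = 5.99e-05 without the first and 0.000544 without the second). It was kept too with the luminal marker mean as a covariate, at a median of -1.02. At this setting 98 of 100 splits called as many interaction lists as the real one, so a kept call does not exclude that single arrays set the shift. Without SD day -9 replicate 1 the median was -0.52, and leaving out both arrays together was not tested. The spread between arrays of a group stays open as a candidate explanation (permutation p = 0.107 for the score over 1400 arrangements), as does a difference in cell division between photoperiods, which could not be separated from it with 3 or 4 arrays per group.

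In LD day -9 replicate 4 and SD day -24 replicate 3, 280 probe sets were low together, with a median of -1.41 against the other 12 arrays. Other probe sets of 70 of the genes were lower too, by -0.49 (95% bootstrap interval over genes -0.58 to -0.37), but 17 of these 117 probe sets belong to the low set by its definition, and the 100 outside it were at -0.39 (-0.50 to -0.27 over 66 genes), which does not separate lower transcript levels from a loss at the probes. The 3-prime to 5-prime difference averaged over 5 control transcripts was higher in this pair than in the other arrays (1.27 against 0.98, one-sided exact permutation p = 0.0220 over 91 pairs), and so it was with actin as the sixth (1.13 against 0.879, the same p), while actin itself, left out for its low signal of 3.92 to 5.54, was alike in both (0.403 against 0.382). By the prediction as first written this p would have counted for shorter RNA or cRNA. SD day -24 replicate 2 was then seen to reach 1.26 as well, without a shared loss of these probe sets, so the explanation is left open. The transcripts were not alike. EIF4E was highest in the pair (4.60 and 4.58), and its 5-prime probe set was lowest there (5.51 and 5.75). GAPDH, at 1.48 and 1.57, lay within the range of the other arrays (1.27 to 1.84). EF1A, cyclophilin and GST were highest in SD day -24 replicate 3, with LD day -9 replicate 4 within the range of the others. The gap of 0.7 that defines the set was chosen after the data had been seen, and no biological explanation other than lower transcript levels was tested, since the pair comes from different photoperiods and days.

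AGA was higher in all 7 SD arrays than in all 7 LD arrays by 1 probe set. Of 100 splits of the arrays within days, the real one included, 10 gave a probe set with a p as small as 6.2e-06, so chance among the probe sets tested may account for it. The second AGA probe set, at 0.14 with an interval up to 0.50, neither shows nor excludes a change of the whole transcript by 0.42. A sequence variant under the first probe set that differs in frequency between the cows of both photoperiods was not tested.

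Among groups of 4 arrays, 17 of 196 tested (list scores, named genes and control transcripts) held 1 array far from the others, where chance gives about 1 in 20, or 9.8. SD day -9 replicate 1 was apart in antigen presentation class I (-0.26), amino acid transport and synthesis (0.26) and skin keratinocyte markers (0.29), and in IGF1 (5.30). LD day -9 replicate 2 was apart in macrophage and dendritic cell markers (0.62), erythrocyte markers (-0.17) and TMEM183A (9.14). SD day -9 replicate 2 was apart in CD68 (6.52), PEBP4 (4.88) and PTPN2 (9.83). SD day -9 replicate 3 was apart in PLA2G7 (6.65), PRSS2 (4.28) and MYNN (6.92). SD day -9 replicate 4 was apart in TMEM183A (10.61) and HNRNPH2 (9.18). LD day -9 replicate 3 was apart in PLXNB2 (5.61) and LD day -9 replicate 4 in IGF1 (4.33).

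Other splits of the same arrays were counted for the number of probe sets at an unadjusted p under 0.05 and for the number of lists called, with the real split included in each count. At day -24 the 10 splits are too few for a share under 0.05: the real numbers were 580 and 4 and the highest others 3244 and 9, and 9 and 6 of the 10 splits gave as many. The split with 3244 sets LD day -24 replicates 2 and 3 and SD day -24 replicate 3 against the rest. The first principal component has the same split: these arrays lay at 12.2, 15.6 and 31.0. The rest of day -24, LD replicate 1 and SD replicates 1 and 2, lay at -62.6, -12.7 and -13.2. The largest axis of variance at day -24 thus does not follow photoperiod. That component comes from the same values, and what underlies it was not tested. At day -9, 20 of 35 splits gave as many probe sets (666, highest other 1330) and 18 as many lists (9, highest other 21). For SD against LD averaged over days, 87 of 100 gave as many probe sets (467, highest other 3191) and 72 as many lists (6, highest other 16). In LD between days, 6 of 35 gave as many probe sets (1795, highest other 2211) and 20 as many lists (6, highest other 14). In SD between days, 15 of 35 gave as many probe sets (1096, highest other 1945) and 6 as many lists (13, highest other 15). For the days averaged over photoperiods, 16 of 100 gave as many probe sets (1853, highest other 3230) and 45 as many lists (8, highest other 17). For the interaction, 55 of 100 gave as many probe sets (997, highest other 4354) and 98 as many lists (3, highest other 14). Chance is excluded in none of the 6 comparisons with enough splits. Some splits gave several times the real number, and whether a structure of the samples other than their groups underlies this was not tested.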

How the results depend on the processing

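The leaving out of 2 arrays together was chosen after the data had been seen, and the other alternatives before. The number of probe sets past the threshold was 0 under all alternatives not named here, with a range of 0 to 1. It was 1 (AGA) for SD against LD averaged over days with 1 surrogate variable, and 1 for the days in SD without the 2 arrays of low signal. The range over single arrays left out was 0 to 1 for these 2 comparisons and 0 to 0 for the other 5. With an unadjusted p under 0.05 and 1.5-fold in place of the adjusted threshold, the counts were 179, 190, 84, 344, 338, 129 and 654 in the order of the report. With a correlation estimated from the data, 0 lists were called in each of the 7 comparisons. For the changes that follow, the cause was not tested. Of the 49 list calls, the adipocyte covariate ended 19, the luminal one 15, the filter at a mean of 5 ended 7, the median over probe sets 2, the fixed block 2, the random block 1, and the omission of the 2 arrays of low signal 16 and of the 2 far arrays 24. With a mean log2 value of at least 5, the interaction had 5 lists. With the adipocyte marker mean as a covariate, LD between days had 3, SD between days 6 and the average over photoperiods 5 lists. In SD, milk proteins were then at -0.0443, milk fat synthesis at -0.0397 and endothelial markers at -0.0473. With the luminal covariate, SD between days had 6 and the average 5 lists. With replicate number as a fixed block, SD against LD at day -24 had 7, the days averaged over photoperiods 14 and the interaction 5 lists. The numbers were not taken to pair the arrays, for which every pair had to correlate above 0.1. The correlation of arrays with the same number, after group means were taken out, lay between -0.313 and 0.331 in 6 pairs of the same photoperiod and between -0.131 and 0.304 in 7 pairs of the same day, with 4 and 3 of them above 0.1, against 2 of 6 other pairs of the same number. A random block gave a consensus correlation of 0.0563. Without the 2 arrays of low signal, day -24 had 2, SD between days 6 and the interaction 7 lists. Without LD day -24 replicate 1 and SD day -9 replicate 1, SD against LD averaged over days had 11, SD between days 2 and the interaction 7 lists, innate defence in SD was at -0.00853, macrophage markers averaged over days were at 0.0151, and milk proteins at day -24 were at 0.0527, as the last were without LD day -24 replicate 1 alone. Without SD day -24 replicate 1 they were at -0.261. Over single arrays left out, the number of lists ranged from 2 to 7, 5 to 10, 4 to 9, 3 to 8, 2 to 15, 8 to 15 and 3 to 8 in the order of the report. In 49 pairs of a call and a left-out array the call was kept and its median moved by more than 1.5 times, to between 0.333 and 3.74 times its value; the report names each. Among kept calls, other settings moved medians by more than that too. Without the 2 far arrays these were, at day -9, innate defence (-0.913), macrophage (-0.110) and neutrophil markers (-0.667), in LD between days involution (0.161) and oxidative phosphorylation (0.0900), in SD the cell cycle (-0.422), in the average over photoperiods lactose (0.0878), the cell cycle (-0.190) and involution (0.0884), and in the interaction the cell cycle (-0.491). Without the 2 arrays of low signal these were oxidative phosphorylation (-0.0700) and fibroblast markers (-0.383) at day -9, endothelial markers in SD (0.226) and oxidative phosphorylation in the interaction (-0.101). With the median over probe sets, endothelial markers at day -9 were at 0.189 and stress genes at 0.185 in SD and 0.183 in the interaction. With a mean of at least 5, stress genes in SD were at 0.154 and innate defence in the average over photoperiods at 0.552. With the fixed block, involution in that average was at 0.252. With the adipocyte covariate, stress genes at day -24 were at -0.112 and endothelial markers averaged over days at 0.187. With the luminal one, innate defence was at 0.368 in LD and 0.175 in the average over photoperiods, and stress genes in SD at 0.0406. The lists of adipocyte and luminal markers were not tested with their own mean as the covariate, since the covariate is made from them. This was decided after a first run, in which the test of 2 of these had turned direction. Over all alternatives, the 49 list calls gave 866 values that kept direction and call, 253 that kept the direction of the test and lost the call, some with a median of the other sign, and 5 in which the test turned direction. Named genes gave 8591 values on the same side and within the spread, 177 that changed sign or moved by more than it, and 2, both of AGA, that came past the threshold. Arrays limit what can be seen near background, and no measure of background per probe set was held.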

Other observations

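All tests in this part were chosen after the data had been seen.

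Transcripts of the major histocompatibility complex (MHC), which present antigens to T cells and are highly variable between animals, were among the probe sets that varied most between arrays. Of 44 MHC probe sets, 24 were among the 500 most variable of all tested probe sets, where chance gives 0.916. A candidate explanation is that cows carry different MHC alleles and that the same cows gave biopsies at both days, which the labels do not state. Over the MHC probe sets, 6 of the 6 day -24 arrays had their highest correlation with a day -9 array of their own photoperiod. Chance would give this with a probability of 0.0156 if the 6 comparisons were independent. They are not, since all use the same day -9 arrays and deviations from shared group means. That value is therefore not the probability of this count. Over the 500 most variable probe sets outside the MHC, 4 of 6 did. The bound for excluding the idea was lowered after that value was seen, since chance alone gives 3 of 6, so this count decides nothing. One of the 2 exceptions, SD day -24 replicate 3, matched LD day -9 replicate 4, with which it shares the low probe sets. The correlations were taken after the mean of each group had been subtracted. A shift of the mean of MHC transcripts with photoperiod therefore cannot give these matches. Other effects of photoperiod on these transcripts were not tested, and repeated cows stay a candidate that the labels do not settle. If cows were repeated, arrays of both days would not be independent.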
